A study of Drosophila melanogaster with 4 samples.

How the data were processed

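The series profiled mono-methylation of lysine 4 of histone H3 (H3K4me1), a mark found at enhancers and beside active promoters, by chromatin immunoprecipitation and sequencing (ChIP-seq) in whole embryos of Drosophila melanogaster. The embryos were of the wild-type Oregon-R strain and were collected 14 to 16 h after egg laying, late in embryogenesis. The antibody was ab8895, in a batch that the labels call new lot 2. Chromatin had been fixed with formaldehyde, per the labels' protocols. There were 2 ChIP libraries and 2 input libraries of genomic DNA. The labels name replicates 1 and 2 of each but do not say whether they came from separate embryo collections, so the spread between replicates may be technical. Per the labels, the input numbered 1 served the ChIP library numbered 2, and the input numbered 2 served the ChIP library numbered 1. Input values were not analysed here. Replicate numbers were taken from the sample titles. Both replicate lists carry the same experiment number, while the labels give the ChIP libraries different numbers, so which list belongs to which library rests on the repository's record of each list's sample. A swap would exchange the names replicate 1 and replicate 2 throughout and leave their means unchanged.

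The values analysed are lists of regions of significant enrichment. One list belongs to each ChIP library, and a combined list covers both replicates. The authors deposited each region with its first and last base, counted from 1 on FlyBase release 5 per the file headers, and with a score. Per the submitters' processing notes Bowtie 0.12.7 was used. The region caller, its threshold, the use of the input and the way the replicates were combined are not given in the sources used here. Sequencing depth is also not given in the sources used here, so no value could be set against a number of reads. The single record that the combined list names as depleted was kept out of all counts of enriched regions.

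The scale of the deposited score is not stated by the authors, and it was settled from the values. Within a list, scores were compared with the logarithm of one constant times a ratio of whole numbers, with denominators up to 20000 and a relative tolerance of 2e-13. In base 2 this held for 7601 of 7601 regions in replicate 1, 7401 of 7401 in replicate 2 and 8218 of 8219 in the combined list. The constant in base 2 was chosen so that the whole numbers behind the scores of short regions came out smallest. The ratios given below depend on this choice. With natural logarithms 0, 0 and 1 scores passed, and with base 10 logarithms 0, 2 and 1 passed. For these other bases distinct scores were counted, and the constant was not chosen in this way. After a random shift of each score by up to one millionth, 1, 0 and 1 passed. On simulated scores made from known counts for 7601 regions, 100% of the ratios were recovered. The deposited scores are therefore treated as log2 values, each list with its own constant. They are given below in log2 units.

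Lists were compared by overlap of at least 1 bp. The chance level came from 1000 circular shifts of the regions of replicate 2 within each sequence, with a fixed seed. Shared base pairs under chance were computed for 200 of these shifts. For regions of at least 20 kb, the other list was shifted 200 times. Such a shift describes these lists and is not a test over biological replicates. Shares of regions have 95% exact Clopper-Pearson intervals, which cover counting error only, and neighbouring regions are not independent. Values for a chromosome arm are the mean ± SD of both replicate lists (n = 2). Values of the combined list are the authors' own and have no SD or n. Arm lengths came from the file headers. Coverage along the 5 large arms (X, 2L, 2R, 3L and 3R) was computed in 1 Mb windows, and the last window of an arm was kept if at least 500000 bp long. The overlap step was tested on simulated lists of 7601 regions, in which 100% of the regions kept on purpose were found again.

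The named regions follow a rule fixed before the data were examined. They are the 10 regions with the highest score and the 10 widest regions of the combined list, and the 3 highest-scoring regions of each replicate that overlap nothing in the other. A comparison of 20 fixed gene lists and a split into promoter, exon, intron and intergenic sequence had also been planned. Neither was made, because the gene table at hand is on release 6 and the region lists are on release 5, and coordinates were not converted. No gene name is therefore given for any region, and the 20 lists have no result here. The comparisons of the lists with each other and of the arms were planned. The views of regions of at least 20 kb, score quintiles, 1 Mb windows, sequence next to the centromere, stretches of the length of chromosome 4, the ranks and rotations of scores on X and the scale of the score were chosen after looking at the data. For the rotations, scores were moved in order along the regions of the large arms, 1000 times, which keeps neighbours together. In all, 7 explanations were tested in the closing section. The test of an offset on X replaced 2 earlier versions, and the limits or comparison sets used to judge 4 other tests, on chromosome 4, pooling, weak enrichment and small whole numbers, were changed after their values were seen. Alternatives covered the overlap rule, the chance model, a stricter score, each replicate alone and, added later, the joining of neighbouring regions, the removal of centromere-proximal sequence and the use of regions supported by both replicates. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures were drawn with matplotlib 3.10.9.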

Results

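H3K4me1-enriched regions were listed for 2 ChIP libraries from 14 to 16 h embryos and for both libraries combined. Replicate 1 had 7601 regions and replicate 2 had 7401. They covered 37.6 Mb and 35.1 Mb, and of the 5 large chromosome arms they covered 30.2% ± 1.48 (SD, n = 2). The combined list had 8219 regions over 42.8 Mb, or 35.4% of the large arms. Regions ranged from narrow to very broad. The median width was 3435 bp in replicate 1 and 3268 bp in replicate 2, and the widest regions measured 50067 bp and 56122 bp. Regions of at least 20 kb numbered 127 in replicate 1, 101 in replicate 2 and 194 in the combined list, where they held 12.7% of the covered length. Wider regions had higher scores. Across regions, Spearman's rho between width and score was 0.82 in replicate 1, 0.80 in replicate 2 and 0.81 in the combined list, and regions are not independent replicates.

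The design first asks how far the replicate libraries marked the same sequence. Of the replicate 1 regions, 6684 of 7601 (87.9%, interval 87.2 to 88.7) overlapped a region of replicate 2. In the other direction 7051 of 7401 (95.3%, interval 94.8 to 95.7) overlapped a region of replicate 1. Circular shifts gave means of 45.2% and 47.4%, and none of the 1000 shifts exceeded 51.1% and 53.7%. The shared sequence came to 33.3 Mb, or 84.5% of the 39.4 Mb covered by either list, against at most 12.7 Mb in 200 of the shifts. No region had the same start and end in both lists. At least 50% of the length was covered by the other list in 127 of 127 regions of replicate 1 that measured 20 kb or more, and in 101 of 101 of replicate 2. In 200 shifts this held for at most 52 and 44 of them.

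Regions without a partner were short and weak. The 917 regions found in replicate 1 alone had a median width of 1707 bp and a median score of 0.48, against 3867 bp and 0.86 for the shared regions of that list. The 350 regions found in replicate 2 alone had medians of 1552 bp and 0.56, against 3422 bp and 0.84. In the lowest quintile of replicate 1 by score, 58.3% of the regions were shared. This share was 83.4% in the next quintile and 98.4%, 99.9% and 99.8% in the upper ones. In replicate 2 the shares rose from 85.4% in the lowest quintile to 93.4% and then to 98.2%, 99.6% and 99.7%. Score rose with width, and wide regions overlap more often by chance, so the rise cannot be put down to score alone. In shifts, a mean of 92.5 of the 127 replicate 1 regions of at least 20 kb overlapped, against 45.2% of all its regions. By region, the strongest exceptions in replicate 1 lay on the unplaced sequence U, at 5425581 to 5427351 with a score of 2.04 and at 5536854 to 5538448 with a score of 1.76, and on 3L at 23664841 to 23667950 with a score of 1.20. In replicate 2 they lay on 2L at 21552351 to 21554425 with a score of 1.96, on X at 8188903 to 8190233 with a score of 1.57, and on 3L at 20327602 to 20329307 with a score of 1.41. The ratios behind these scores, in lowest terms, are 5 to 1, 33 to 8 and 143 to 51 in replicate 1 and 41 to 12, 13 to 5 and 7 to 3 in replicate 2. Each of these 6 regions overlapped a region of the combined list.

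**Figure D1:**
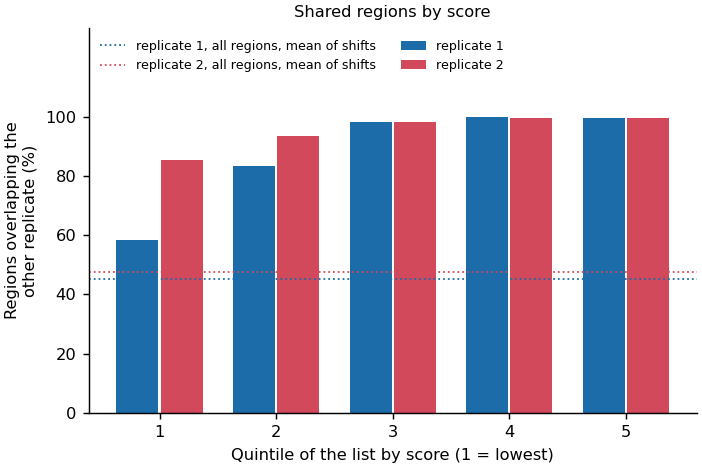
Bars give the percentage of regions in each quintile of a list, ordered by score from lowest (1) to highest (5), that overlap a region of the other replicate, and dotted lines give the mean of the circular shifts over all regions. The lowest quintile stood at 58.3% in replicate 1 and 85.4% in replicate 2, and the highest at 99.8% and 99.7%.

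Regions that ranked high by score in one replicate also ranked high in the other. For 5495 regions matched one to one, Spearman's rho was 0.92 for the score and 0.94 for the width. This matched set leaves out regions that either list split into several. Over all 7400 overlapping pairs, which was the planned measure and includes split regions, rho for the score was 0.84. These correlations run across regions within a single pair of libraries.

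**Figure D2:**
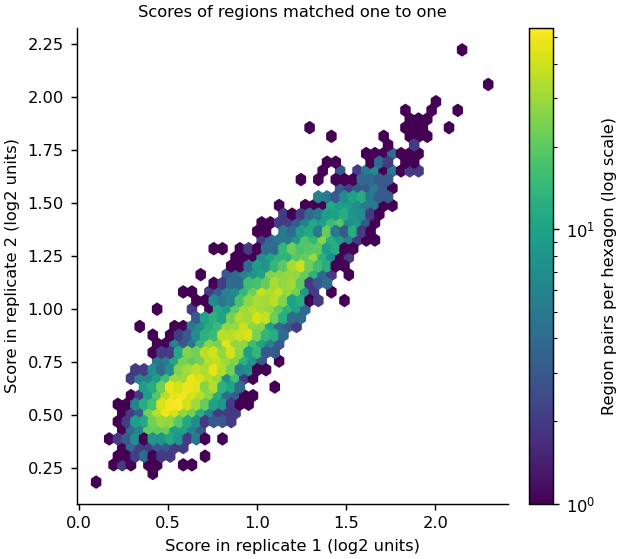
Each hexagon counts region pairs matched one to one by their score in replicate 1 (x axis) and replicate 2 (y axis), both in log2 units with a constant of its own for each list, on a log colour scale. The 5495 pairs rise together, with a rho of 0.92.

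The combined list, which covers the same 2 libraries and is not independent of them, was compared with the lists of the single libraries. It held 99.9% of the replicate 1 regions and 99.8% of the replicate 2 regions, including 911 of the 917 regions found in replicate 1 alone and 332 of the 350 found in replicate 2 alone. Of its 8219 regions, 5957 (72.5%, interval 71.5 to 73.4) overlapped both lists and held 90.9% of its length. A further 813 overlapped replicate 1 only and 278 overlapped replicate 2 only. The remaining 1171 (14.2%, interval 13.5 to 15.0) overlapped neither, and held 3.85% of the length. The latter were short, with a median of 1319 bp, and their median score was 0.35 against 0.82 for regions found in both. The shortest region had 1001 bp in the combined list, 1302 bp in replicate 1 and 1301 bp in replicate 2. In 749 cases a combined region spanned 2 or more regions of replicate 1, and in 944 cases it spanned 2 or more of replicate 2.

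All of the 10 widest combined regions were found in both replicates, which the shared libraries and the width of these regions made likely. The widest lay on 2R at 8832629 to 8912475 (79847 bp, score 1.54), and 3 regions of each replicate covered 99.5% and 98.8% of it. The next were on 3L at 17948697 to 18018218 (69522 bp, score 1.42), on 3R at 9795505 to 9862199 (66695 bp, score 1.20) and on 3R at 12029401 to 12085811 (56411 bp, score 1.81). On X, the region at 12607190 to 12661460 measured 54271 bp with a score of 1.59. The region on 3R at 21820768 to 21870907 measured 50140 bp with a score of 1.48, and that on 2R at 6414979 to 6463990 measured 49012 bp with a score of 1.49. On 2L, the region at 3811689 to 3858241 (46553 bp, score 1.15) was covered to 94.9% by 4 regions of replicate 1 and to 81.9% by 7 regions of replicate 2. The last of this set were on 2R at 19493872 to 19540048 (46177 bp, score 1.28) and on 3L at 21020417 to 21064874 (44458 bp, score 1.09).

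**Figure D3:**
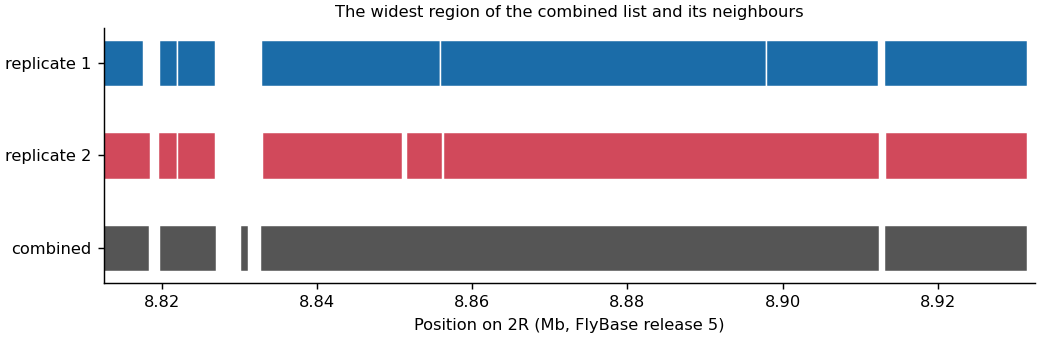
Bars show the enriched regions of each list on 2R around the widest combined region, drawn to scale in Mb of release 5, with white lines where separate regions meet. The combined region of 79847 bp spans 3 regions of replicate 1 and 3 regions of replicate 2.

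Of the 10 combined regions with the highest score, 7 were found in both replicates and 4 of these were on X. The X regions lay at 2175406 to 2203883 (score 2.20, with 2.30 in replicate 1 and 2.08 in replicate 2), at 1831922 to 1849969 (score 2.18, with 2.15 and 2.22), at 12466777 to 12478933 (score 1.98, with 1.99 and 1.97) and at 3636718 to 3648276 (score 1.92, with 1.95 and 1.86). On 3L, regions stood at 20998367 to 21008928 (score 2.05) and at 10658108 to 10680132 (score 1.93), and on 3R a region stood at 13523964 to 13543596 (score 1.95). These 7 regions were 10562 to 28478 bp wide. The other 3 regions overlapped neither replicate list and were at most 1009 bp wide. They lay on the unplaced sequence U at 9260354 to 9261354 (score 3.50), on 3L at 19764437 to 19765437 (score 2.92) and on 2L at 4608158 to 4609166 (score 2.17). The ratios behind their scores, in lowest terms, are 12 to 1, 8 to 1 and 19 to 4.

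The distribution over chromosomes was then compared. Among the 5 large arms the density of regions ran from 58.2 ± 1.66 per Mb on 2L to 64.8 ± 1.17 per Mb on 2R (SD, n = 2). The covered share was 33.0% ± 1.39 on 2R, 32.0% ± 1.25 on X, 30.4% ± 1.49 on 3R, 29.3% ± 1.54 on 3L and 26.4% ± 1.70 on 2L. In density and in covered share the difference between 2R and 2L exceeded the spread between replicates, and 2R was above 2L in both libraries. Chromosome 4, the small dot chromosome whose chromatin is largely heterochromatic, had short regions. Their median width was 2273 ± 18.7 bp, against medians over the large arms of 3476 bp in replicate 1 and 3297 bp in replicate 2. Density on chromosome 4 was 85.8 per Mb in replicate 1 and 73.2 per Mb in replicate 2, or 1.37 and 1.20 times that of the large arms. In replicate 1 it exceeded all 86 stretches of the same length on the large arms, and in replicate 2 it exceeded 66 of the 86. The margin in replicate 1 was small, since the densest stretch had 85.1 per Mb. In replicate 2 the densest had 91.7 per Mb. Stretches were laid end to end from the first base of each arm, and other starting points were not tried. The direction turned among strong regions: in the 50% of combined regions with the highest scores, the density of chromosome 4 was 0.806 times that of the large arms. Its covered share, 26.0% ± 3.12, differed from that of 2L, the least covered large arm, by less than the spread between replicates. Against all large arms together, the covered share of chromosome 4 was lower, at 0.905 times theirs in replicate 1 and 0.818 times in replicate 2. The median score on chromosome 4 was 0.59 ± 0.049, the lowest of the 6.

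Regions on X had the highest median score of the 5 large arms in both replicate lists, 0.89 ± 0.016 (SD, n = 2). The autosomal arms followed with 0.83 ± 0.0070 on 2R, 0.81 ± 0.020 on 3R, 0.77 ± 0.021 on 3L and 0.77 ± 0.017 on 2L. X minus all autosomal regions came to 0.10 in replicate 1 and 0.099 in replicate 2, but to 0.038 in the combined list, where 2R (0.681) and not X (0.678) had the highest median. Of the 100 highest-scoring regions on the large arms, X held 36 in replicate 1, 42 in replicate 2 and 35 in the combined list, with intervals of 26.6 to 46.2%, 32.2 to 52.3% and 25.7 to 45.2%, while 19.0%, 19.5% and 19.3% of all regions on these arms were on X. When scores were rotated along the regions, 57, 23 and 69 of 1000 rotations gave X as many in replicate 1, replicate 2 and the combined list, and 17, 27 and 180 gave a median difference as large. With 1 X among 5 large arms, an exact permutation of arms cannot give p below 0.2.

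**Figure D4:**
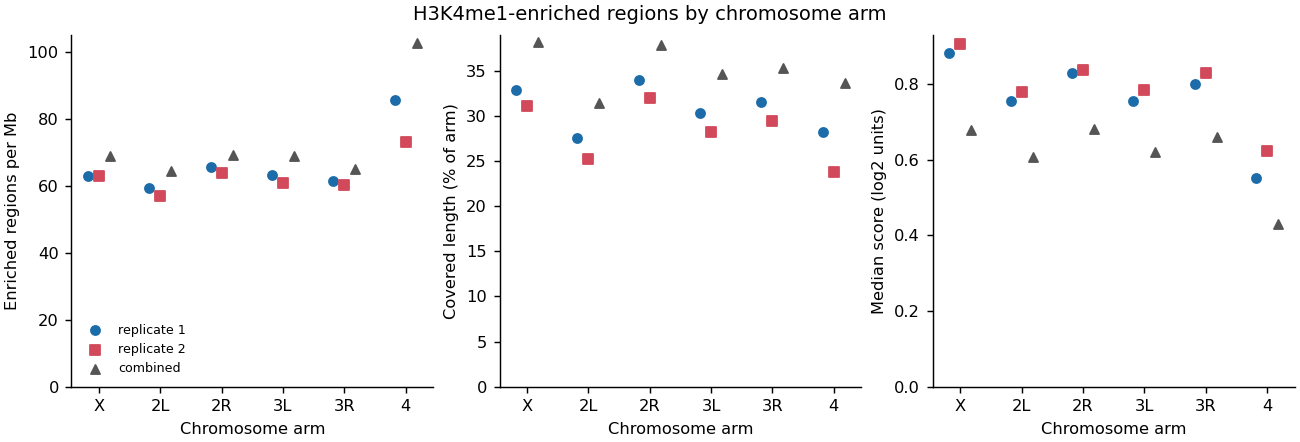
Points give, for each of the 5 large arms and chromosome 4, the number of enriched regions per Mb (left), the covered percentage of the arm (middle) and the median score in log2 units (right) in replicate 1, replicate 2 and the combined list. Chromosome 4 has the highest density and the lowest median score, and X has the highest median score in both replicates.

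Coverage varied along the arms far more than between replicates. Over 119 windows of 1 Mb the covered share ranged from 0.85% to 52.6% with an SD of 9.37 between windows, while the median SD between replicates was 1.44. Pearson's r between replicates across windows was 0.99, and windows within a library are not independent replicates. Replicate 1 covered more than replicate 2 in 119 of 119 windows. Read depth was not known, so the part that unequal depth may have in this was not computed. The highest windows were the distal end of 3L from 1 to 1000000 (52.6% ± 1.45), 3R from 5000001 to 6000000 (47.9% ± 0.831), 2R from 3000001 to 4000000 (46.5% ± 1.95), 3R from 12000001 to 13000000 (44.5% ± 2.89) and X from 1000001 to 2000000 (44.2% ± 0.492). The lowest were 3L from 24000001 to 24543557 (0.85% ± 0.62), 3L from 23000001 to 24000000 (2.35% ± 0.930), 2R from 1 to 1000000 (3.87% ± 0.701), 2L from 22000001 to 23000000 (6.46% ± 1.27) and, inside an arm, 2L from 17000001 to 18000000 (9.09% ± 0.612).

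The 2 Mb at the centromere end of the assembled arm, here called next to the centromere, had low coverage on 4 of the 5 large arms. Heterochromatic sequences held apart from the arms, such as 3RHet, are not included. How far each assembled arm reaches towards its centromere was not examined. Coverage was taken over the full assembled length, and the part to which reads can be mapped was not computed. Low coverage therefore need not mean absence of H3K4me1. Coverage there was 6.31% ± 0.718 on 3L against 31.3% ± 1.61 on the rest of that arm, 10.5% ± 0.789 on 2R against 35.3% ± 1.45, 13.6% ± 0.585 on X against 33.8% ± 1.31, and 14.2% ± 1.16 on 2L against 27.5% ± 1.75 (SD, n = 2). On 3R the direction was the opposite, with 36.5% ± 1.38 at this end of the assembled arm and 30.0% ± 1.50 on the rest. Each of these differences exceeded the spread between replicates. An exact sign-flip test over 5 arms cannot give p below 0.0625, so none is reported. The longest stretch of a large arm without any combined region was on X from 21505973 to 21843216, a length of 337 kb. In replicate 1 the longest was also on X (337 kb), but in replicate 2 it was on 3L from 24024399 to 24543557 (519 kb).

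**Figure D5:**
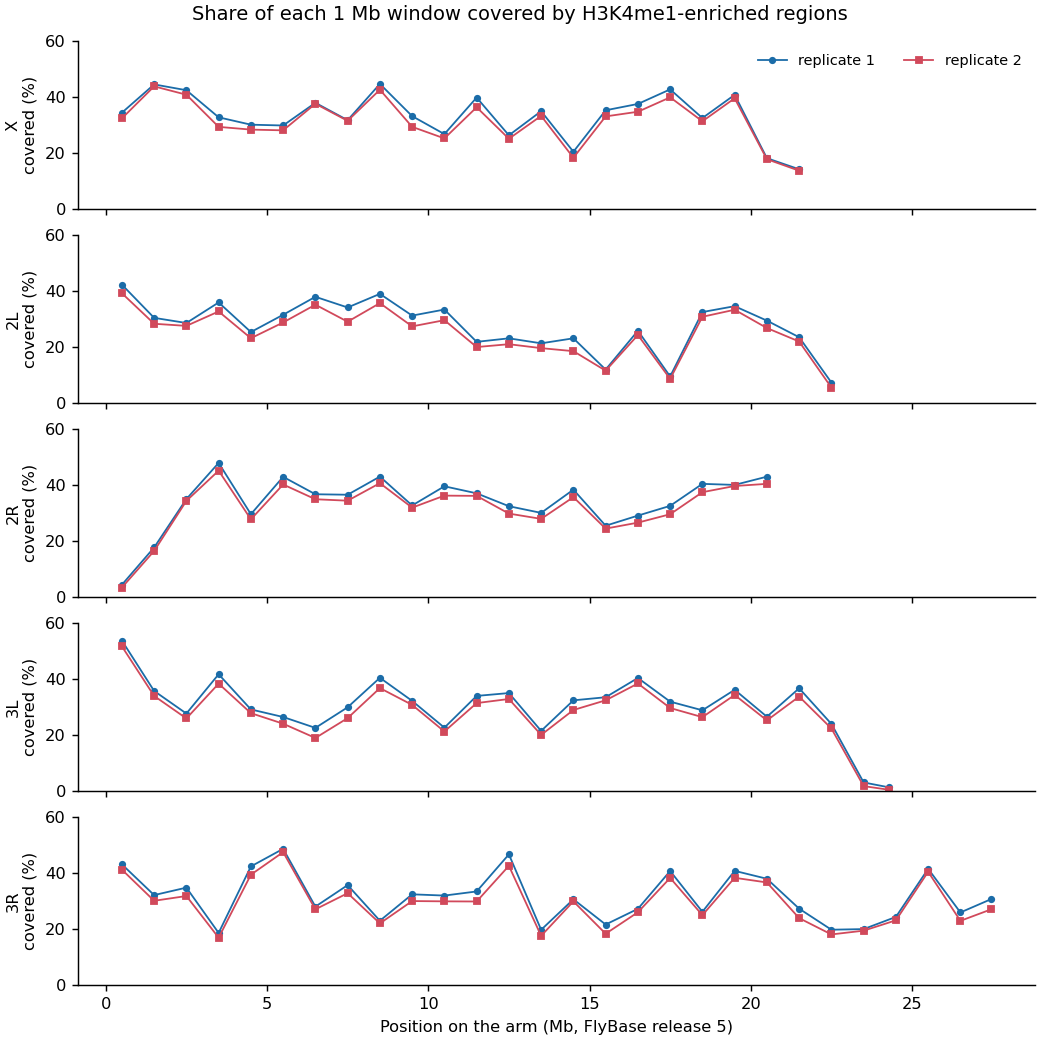
Each panel follows one large arm, with position in Mb of release 5 on the x axis and the percentage of each 1 Mb window covered by enriched regions on the y axis, for replicate 1 and replicate 2. Both lines fall towards the centromere on X, 2L and 3L (right end) and 2R (left end), but not on 3R (left end).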

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

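The count of regions supported by both replicates was chosen after the data were seen. The comparison of arms left out 7 heterochromatic and unplaced sequences (2LHet, 2RHet, 3LHet, 3RHet, XHet, YHet and U), which together measure 19.3 Mb. The combined list had 73 regions there. They were flagged because a count of 0 allows at most 3, a limit that takes no account of the length of these sequences. Another unplaced sequence, Uextra, measures 29.0 Mb and had 0 regions in each of the 3 lists, and whether it was searched is not given in the sources used here. Replicate 1 had 47 regions on the 7 sequences and replicate 2 had 41. Density in the combined list was 3.78 regions per Mb, or 1.51 with Uextra included, against 67.3 per Mb on the 5 large arms. The covered share of the 7 sequences was 0.882%, against 35.4% of the large arms, so together they were poor in listed regions. Both measures were taken over the full length, and the part to which reads can be mapped was not computed. Few regions therefore need not mean absence of H3K4me1. Both replicates supported 34 of the 73 (46.6%), against 72.7% of the combined regions on the 6 arms. XHet stood apart from the rest, with 9 regions in each replicate and a covered share of 17.7% in replicate 1 and 13.4% in replicate 2.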

How the results depend on the processing

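Joining of regions, removal of centromere-proximal sequence, regions supported by both replicates and removal of the lowest scores were chosen after the data were seen, and the other alternatives before. Of 42 values under alternatives, 12 moved by less than a spread, 29 moved by more without a change of direction and 1 changed direction. The spread was not a single measure. For shares of regions the split follows the exact intervals, which cover counting error only. For values of arms it follows the SD between replicates. The measure used for chance levels and for the score correlation is not given here. The counts therefore do not set all 42 values against variation between replicates. The share of replicate 1 regions found in replicate 2 was 86.2% when 50% of the region had to be covered and 80.9% with 50% reciprocal overlap. For replicate 2 these values were 94.2% and 83.0%, and it was 92.6% in the top 50% of each list by score and 93.4% without scores under the lower quartile. Uniform placement put the chance level for replicate 1 at 42.9%. The Spearman correlation of scores between replicates rose to 0.92 for pairs with 50% reciprocal overlap. Combined regions supported by both replicates fell to 69.7% when 50% had to be covered. The density of chromosome 4 over the large arms, 1.53 in the combined list, was 1.20 to 1.37 in either replicate alone, 1.40 after joining and 1.30 for regions supported by both. It turned to 0.806 in the top 50% by score, a choice that removes more regions from chromosome 4, whose scores are lower. The covered share of chromosome 4 over the large arms, 0.949, was 0.818 to 0.905 in either replicate alone, 0.641 in the top 50% and 0.852 for regions supported by both. Its median width over that of the large arms, 0.623, was 0.650 to 0.693 in either replicate, 0.806 in the top 50%, 0.667 after joining and 0.658 for regions supported by both. The covered share of X over the autosomal arms was 1.07 to 1.09 in either replicate, 1.17 in the top 50%, 1.12 without the sequence next to the centromere and 1.09 for regions supported by both. X minus autosome median score, 0.038, was 0.099 to 0.10 in either replicate, 0.059 in the top 50%, 0.043 without the sequence next to the centromere and 0.098 for regions supported by both. Of the combined regions on X, 16.9% overlapped neither replicate, against 12.0 to 14.2% on the autosomal arms. Beyond this, the cause of the moves was not tested. Replicate overlap and score agreement need both libraries and have no value with either left out. Other gene margins, promoter widths and matching of random lists, foreseen for gene lists and for promoter, exon and intron shares, were not run, because those results were not made. No paired analysis was possible because input values were not analysed here. Read depth was not known for any library, so what depth limits could not be computed. The whole numbers behind the scores were larger in replicate 1 than in replicate 2. Their upper quartiles per kb were 272 against 176 for the numerator and 126 against 113 for the denominator. They are in lowest terms and are not read counts. If they come from reads, unequal depth may share in the differences between the replicate lists, which was not tested.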

Other observations

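The joining of regions on chromosome 4 and the comparison of X scores within width deciles were tests added once the data had been looked at but before their own results were seen, and how the spread entered the test on chromosome 4 was changed after its result. The other 5 tests in this part, and the limits used to judge them, were chosen after.

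The combined list names a single region as depleted, on 2L at 4402899 to 4404530, with a score of -0.0029. Replicate 1 lists an enriched region inside it, at 4403199 to 4404512 with a score of 0.29, and replicate 2 lists none there. This region was chosen after its values were seen.

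A set of 1171 combined regions overlapped neither replicate list. Of them 51.7%, or 605 regions, were as long in the combined list as the shortest replicate region or longer. This cannot exclude a shorter minimum length as the reason, because the length of the same stretch in a single library is not known. Their median of 1319 bp lies close to the replicate minimum of 1301 bp. Their scores were low, with 98.0% below the median of the regions found in both, but so were those of regions found in a single replicate (99.5% of 1091), so weak enrichment that passes only when both libraries are used together stays open. A score above 1 was found in 16 of them, and in 100% of these the ratio behind the score needs no whole number above 100, against 19.2% of 1076 regions of the same range of width (1001 to 1984 bp) that also overlap neither and score at most 1. Regions found in both with a score above 1 offer no comparison, since 0 of them measure under 2 kb. High scores of these 16 short regions may rest on few reads, but this contrast cannot decide it. A high score without overlap in either replicate list may by itself favour small whole numbers. The comparison regions score at most 1 and were not chosen in that way. Ratios are known in lowest terms and are not read counts, and no biological explanation was tested.

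If the whole numbers behind the scores come from reads, their size bears on how the combined list was made. Pooling of both libraries is a candidate explanation. The upper quartile of the denominator per kb in the combined list was 0.995 of the sum of both replicates, but that of the numerator was 0.903, outside a limit of 5% for both. A wider limit for the numerator, tried earlier, had let this pass, so pooling is left open. The quartiles also run over unlike sets of regions. The combined list holds 1171 regions, with a median score of 0.35, that overlap neither replicate list, so the lower numerator need not speak against pooling.

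Chromosome 4 had many short regions. Splitting of wide domains by short gaps was tested by joining regions at most 1 kb apart, with a density ratio of at most 1.1 in both replicates as the sign of splitting. The ratio of chromosome 4 to the large arms was then 1.34 in replicate 1 and 1.19 in replicate 2, a mean of 1.27, against 1.37 and 1.20 before joining. Both lie above 1.1, and the mean does so by more than the SD of 0.111 between replicates, which argues against gaps of up to 1 kb as the whole cause. Joining removed 7.59% and 6.50% of the excess over an equal density in the replicates and 24.9% in the combined list, so a part remains possible. Judging by the mean was chosen after the result was seen. Replicate 2 on its own lies above 1.1 by less than the SD, and by less than the full difference of 0.157 between replicates, so it alone would not decide. No biological explanation was tested, and wider gaps were not joined.

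Scores on X exceeded those on the autosomal arms in both replicates. A larger width of X regions is argued against by the widths themselves, whose medians were no larger on X (3469 against 3476.5 bp in replicate 1, 3292.5 against 3298 bp in replicate 2), although the means were (5229 against 4937 bp, 4934 against 4733 bp). Matching on width could therefore move the median difference little, and within width deciles X was higher by 0.089 on average (0.081 in replicate 1 and 0.097 in replicate 2), in 10 of 10 deciles in each replicate. In the combined list the difference was smaller, 0.051, with X higher in 8 of 10 deciles. A single offset over all of X, such as a different X dose in ChIP and input, was judged in 3 ways, each chosen after the one before. The first set differences at the lower quartile (0.077 and 0.080) against those at the upper quartile (0.11 and 0.10), which spoke against an offset but was set aside because a threshold shapes the lower end of a list. The next used equal ranks per Mb, where X was higher by 0.13 in both replicates at rank 5 and by 0.090 and 0.10 at rank 40, a mean fall of 0.036, which exceeded the spread between replicates and again spoke against an offset. The last also allowed for the same value on single autosomal arms, which ranged from -0.058 to 0.039 over both replicates. The fall on X was 0.042 in replicate 1, above this range, and 0.031 in replicate 2, inside it. With that the offset cannot be told apart from differences between arms. In the combined list X was higher by 0.12 at rank 5 and by 0.050 at rank 40. This fall of 0.066 lies outside the autosomal range of -0.050 to 0.037 in that list. It does not decide the question, because that list covers the same 2 libraries, has no replicates and holds X as 1 of only 5 large arms. No biological explanation was tested, since the labels name no sex.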
